A study of Homo sapiens with 12 samples.

How the data were processed

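RNA of 12 libraries of K-562 cells in 3 media was analysed, 4 per medium. Per the labels' protocols, cells were seeded at 100000 per mL in 25 mL, cultured for 72 h, treated for 24 h and washed with PBS, RNA was extracted with an RNeasy Plus kit, and stranded mRNA libraries were made with a TruSeq kit. The deposited table holds a normalized signal per gene and library: read counts divided by a size factor per library, by the authors. Per the submitters' processing notes, the tools named are STAR, featureCounts 1.6.1, DESeq2 1.24.0, R 3.6.0, FastQC 0.11.5 and MultiQC 0.9, with the genome build hg38. The gene annotation and the strand setting of the counting are not given in the sources used here. In each column 100% of the values were whole multiples of the value of a single read (tolerance 0.001), so the reads were recovered for count tests. The size factors of this normalization assume that most genes do not differ between libraries.

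The table has 58381 entries. Those without a gene name, 20930 in all (20552 blank and 378 written as NA), took 0.588% to 0.731% of a library's reads and were kept out of the tests of named genes. Entries that share a symbol, 56 in all, were dropped, and chrY genes and XIST were left out of the tests, which left 37035 genes. Recovered depth, counted over all entries, was 18333598 to 32618806 reads per library with a mean of 24563031, and mitochondrially encoded genes took 1.57% to 3.28% of the signal of the genes kept. Replicate libraries differed by more than sampling noise: the chi-square per degree of freedom over genes was at least 14.9 for every pair of libraries in a medium, so none was counted as a repeat of another.

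The main test was limma with a mean-variance trend on log2(value + 1), over 12811 genes with a mean of at least 10, in a single fit of all 12 libraries with 9 residual degrees of freedom and no block. Tests were two-sided with Benjamini-Hochberg adjustment and a threshold of 0.05. Gene lists, 29 fixed in advance, were tested with limma's camera at a preset correlation of 0.01 where at least 5 members were tested, which left 27, and again with an estimated correlation, under which 0 lists passed in any comparison. Of the list members 40 were matched through an older symbol and 4 were not matched. The choices of tests, lists, alternatives and the rule for named genes were made before the data were examined. That rule named, per comparison, the 8 largest rises and 8 largest falls among called genes with a mean of at least 50 and the same sign in 4 batches, up to 2 called members of each list with the smallest p, the genes HBG1, HBG2, HBZ, GATA1, KLF1, TFRC, KIT, MYC, HMGCS1, LDLR, PLIN2, ANGPTL4, CPT1A, TXNIP and ASNS, and, where fewer than 5 genes passed, the 5 with the smallest p. ANGPTL4 had a mean under 10 and was not tested. List members named beyond that rule, and COL4A1 in the comparison of BeWo-conditioned with unconditioned medium, KRT7, DSP and DHRS2, were chosen after their values were seen.

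The labels mark a shared batch number, so libraries of the same number were taken as paired. Deviations from the group means correlated between libraries of the same batch with r from 0.0842 to 0.747 (median 0.388, 12 pairs) and between different batches with a median of -0.108 (36 pairs). The fit with the batch as a block, with 6 residual degrees of freedom, is given beside a result where it changes a call or moves a count by over 1.5 times. No source states that the replicates came from separate cultures, so the p-values measure only the spread between these samples, which may be technical. Alternatives were the block, other pseudocounts and filters, TMM factors and quantile normalization, fits of only the groups compared or without the variance trend, edgeR's quasi-likelihood test and DESeq2 on the recovered reads, and leaving out each library or batch. A correction for GC content and transcript length, the omission of genes near 0 in unconditioned medium, batch omission with the block kept, the estimated correlation with the block, and library and batch omission for the lists and the overlap were added after the data were seen.

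The fits were tested on simulated counts for the 12811 genes of the comparison of BeWo-conditioned with unconditioned medium, with 50 genes changed at each fold. Limma without the block recovered 0% at 1.25-fold, 40% at 1.5-fold, 90% at 2-fold and 100% at 4-fold with 0 false calls, and with the block 36%, 88%, 100% and 100% with 14 false calls. False calls with the block were 17 for edgeR and 23 for DESeq2. Ratios of summed reads carry exact 95% intervals that cover counting error only, and a group with 0 reads was set to a floor of 3 reads over the group. Gene positions come from the GENCODE annotation of hg38 and were found for 121 of 121 genes looked up. Software was R 4.3.3, limma 3.58.1, edgeR 4.0.16, DESeq2 1.42.0, Python 3.11.15, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3 and matplotlib 3.10.9.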

Results

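RNA was sequenced from K-562 cells, a line derived from a chronic myeloid leukaemia and called a hematopoietic stem cell line in the labels. The series asks whether medium from placental cells changes the transcriptome of such cells. Its 12 libraries fall into 3 media with 4 libraries each. The first medium was unconditioned. The second had been conditioned by BeWo cells, a choriocarcinoma line used as a model of placental trophoblast. The third was BeWo-conditioned medium with 10 µM MEHP, a phthalate metabolite, and the labels do not say whether MEHP was present while the BeWo cells conditioned the medium or was added afterwards. Exposure lasted 24 h, after 72 h of culture. The deposited normalized counts correspond to 18333598 to 32618806 reads per library. Mean depth was 25215276 ± 2634564 reads in unconditioned medium, 23928394 ± 1292816 in BeWo-conditioned medium and 24545425 ± 5946370 with MEHP (SD, n = 4 each). The labels give each library a batch number from 1 to 4 that equals its replicate number and is shared by the 3 media. Values below are normalized read counts as mean ± SD (n = 4), and log2 fold changes are given ± SE on the log2(value + 1) scale, which understates changes of low genes. The libraries are written U1 to U4 for unconditioned medium, B1 to B4 for BeWo-conditioned medium and M1 to M4 for that with MEHP, the digit being the batch. Where a gene or list lost its call when a single library was left out, each such library stands in parentheses with the adjusted p, or its range, after leaving it out. These omissions used the fit without the block, which ignores the pairing, so a lost call does not show that the paired difference rests on that library. With the block kept, only whole batches were left out, and those results are given as counts of genes.

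Transcripts of placental trophoblast were present in the libraries from BeWo-conditioned medium. CGA, which encodes the alpha subunit of chorionic gonadotropin, averaged 0.223 ± 0.445 in unconditioned and 442 ± 239.8 in BeWo-conditioned medium, a rise of 8.34 ± 0.69. MMP2, a matrix metalloproteinase gene outside the trophoblast list, went from 0.874 ± 1.18 to 64.5 ± 26.0, a rise of 5.26 ± 0.63. The limma adjusted p was 7.45e-05 for CGA and 0.00191 for MMP2, and the difference had the same sign in 4 of 4 batches. In reads, CGA had 1752 against 1, a depth-corrected ratio of 1886 (95% interval 338 to 74554), and MMP2 had 251 against 4, a ratio of 67.6 (95% interval 26.1 to 249.9). Of these MMP2 reads in unconditioned medium 3 were in U3 and 1 in U4, so the ratio depends on U3. Intervals and floors cover counting error only. CGA lies on chromosome 6, 87085498 to 87095406, minus strand, and MMP2 on chromosome 16, 55389700 to 55506691, plus strand (hg38, both protein-coding).

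Of the 34 trophoblast and BeWo genes fixed as a list, 14 were abundant enough to test, and 4 rose and 0 fell: CGA, GATA3, CYP19A1 and PGF (6 and 0 adjusted over the list alone, 7 and 0 with the block). The keratin members KRT8, KRT18 and KRT19, which had the most reads in unconditioned medium, were not among them, with depth-corrected ratios of 0.911, 1.07 and 1.02. The transcription factor gene GATA3 rose by 2.39 ± 0.44 on the log2 scale (limma adjusted p = 0.00762), with 30 reads against 3 and a ratio of 10.8 (95% interval 3.35 to 55.1). Aromatase, encoded by CYP19A1, rose by 2.33 (limma adjusted p = 0.0429), and placental growth factor, PGF, by 2.25 (limma adjusted p = 0.0211). CYP19A1 (U1, U3, U4, B2, B3, limma adjusted p 0.078 to 0.124) and PGF (U3, B3, limma adjusted p 0.0739 to 0.0769) lost their calls without 1 library. The list was shifted upward in limma's camera test (adjusted p = 0.00296, and adjusted p = 0.274 with an estimated correlation). In unconditioned medium 20 of the 34 members had at most 3 reads over the group. Of these, 9 exceeded 9 reads in BeWo-conditioned medium, against 0 of 3 lymphoid, 0 of 5 myeloid and 0 of 11 megakaryocyte members that were as silent in unconditioned medium. Some further genes were chosen after their values were seen, with the floor taken as 3 reads over the group: COL4A1, a collagen IV chain, had 40 reads against 0 and was at least 14.4-fold higher against that floor (exact 95% lower limit 11.1), KRT7, a keratin, had 31 against 0 and was at least 11.1-fold higher against it (exact 95% lower limit 8.52), and DSP, a desmosome gene, had 73 against 3, a ratio of 26.2 (95% interval 8.62 to 130.0).

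**Figure D1:**
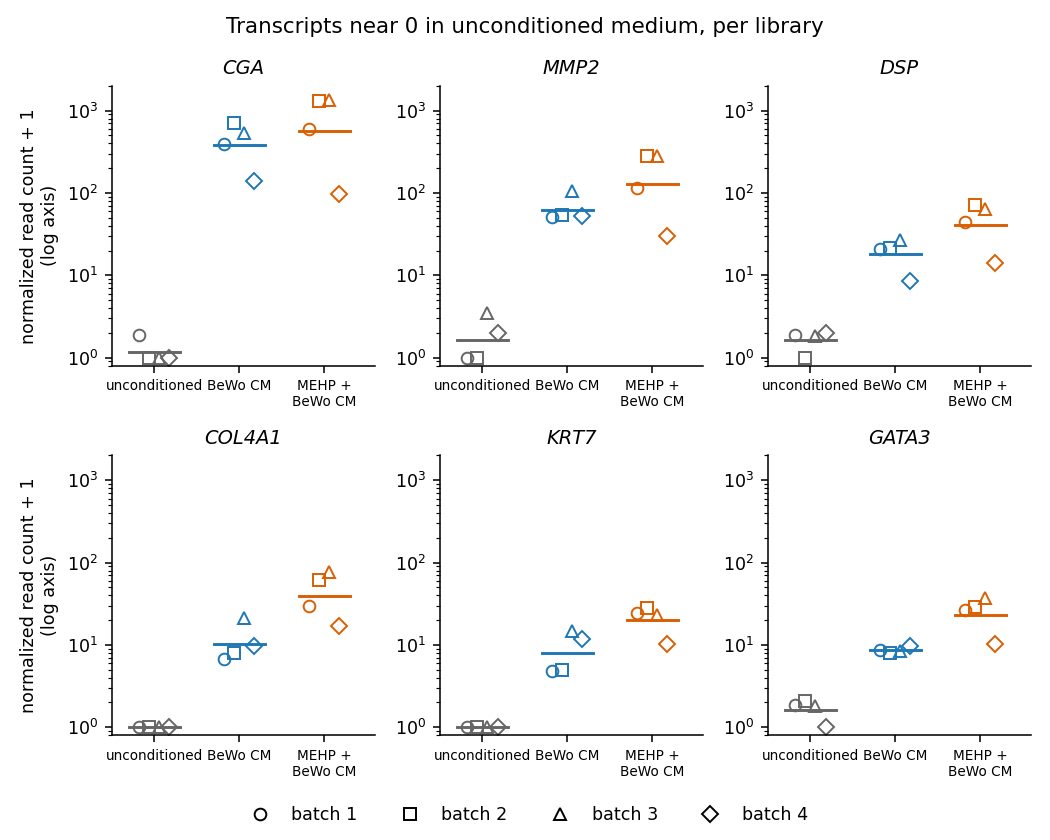
Normalized read counts (plus 1, log axis) of CGA, MMP2, DSP, COL4A1, KRT7 and GATA3 in the 3 media. Points are libraries marked by batch and lines the mean of 4 log2 values, and CGA was between 0 and 0.89 in the unconditioned libraries and at least 97.2 in all libraries with BeWo-conditioned medium.

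Genes that K-562 cells express also changed in BeWo-conditioned medium, in the libraries where CGA had 1752 reads against 1. KIT, the stem cell factor receptor (chromosome 4, 54657918 to 54740715, plus strand), rose from 110.0 ± 17.3 to 369.8 ± 148 (1.67 ± 0.32, limma adjusted p = 0.0098). S1PR3, a receptor for sphingosine phosphate, rose from 139.6 ± 32.2 to 475 ± 166 (1.72 ± 0.29, limma adjusted p = 0.00555). CRYBG1 rose by 1.91 ± 0.31, HMCN1 by 1.74 ± 0.46, PAPPA, a pregnancy-associated plasma protein, by 1.70 ± 0.44 and YPEL4 by 1.67 ± 0.40. The mitochondrial carrier gene SFXN2 (chromosome 10, 102714538 to 102743492, plus strand) went from 337 ± 90.9 to 101 ± 39.7 (-1.78 ± 0.28, limma adjusted p = 0.0045), and PYCR3, of proline synthesis, from 548 ± 42.7 to 226 ± 74.6 (-1.32 ± 0.21, limma adjusted p = 0.0045). Among the 8 largest falls were also VPS9D1-AS1 (-1.82 ± 0.30), CARD9 (-1.51 ± 0.41), ACE (-1.49 ± 0.36), SNAI3-AS1 (-1.19 ± 0.23), DBNL (-1.18 ± 0.16) and ARFRP1 (-1.17 ± 0.16). VPS9D1-AS1 and SNAI3-AS1 are antisense genes, and the strand setting of the counting is not given in the sources used here. Reads of the opposite gene therefore cannot be told apart from theirs. The same limit can apply to other named genes that overlap a gene on the opposite strand. Examples are YPEL4 (with CLP1), DBNL (PGAM2), ARFRP1 (ZGPAT), FADS1 (FADS2), PCK2 (NRL) and DHFR (MSH3). HMCN1 (U1, U2, U3, U4, B3, B4, limma adjusted p 0.0632 to 0.115) and PAPPA (U2, U3, U4, B1, B3, limma adjusted p 0.0583 to 0.112) lost their calls without 1 library. YPEL4 (U2, U3, U4, B3, B4, limma adjusted p 0.0506 to 0.085) and CARD9 (U1, U3, U4, B2, B3, B4, limma adjusted p 0.0716 to 0.123) lost their calls without 1 library. ACE (U1, U3, U4, B2, B3, B4, limma adjusted p 0.0542 to 0.0881) lost its call without 1 library.

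**Figure D2:**
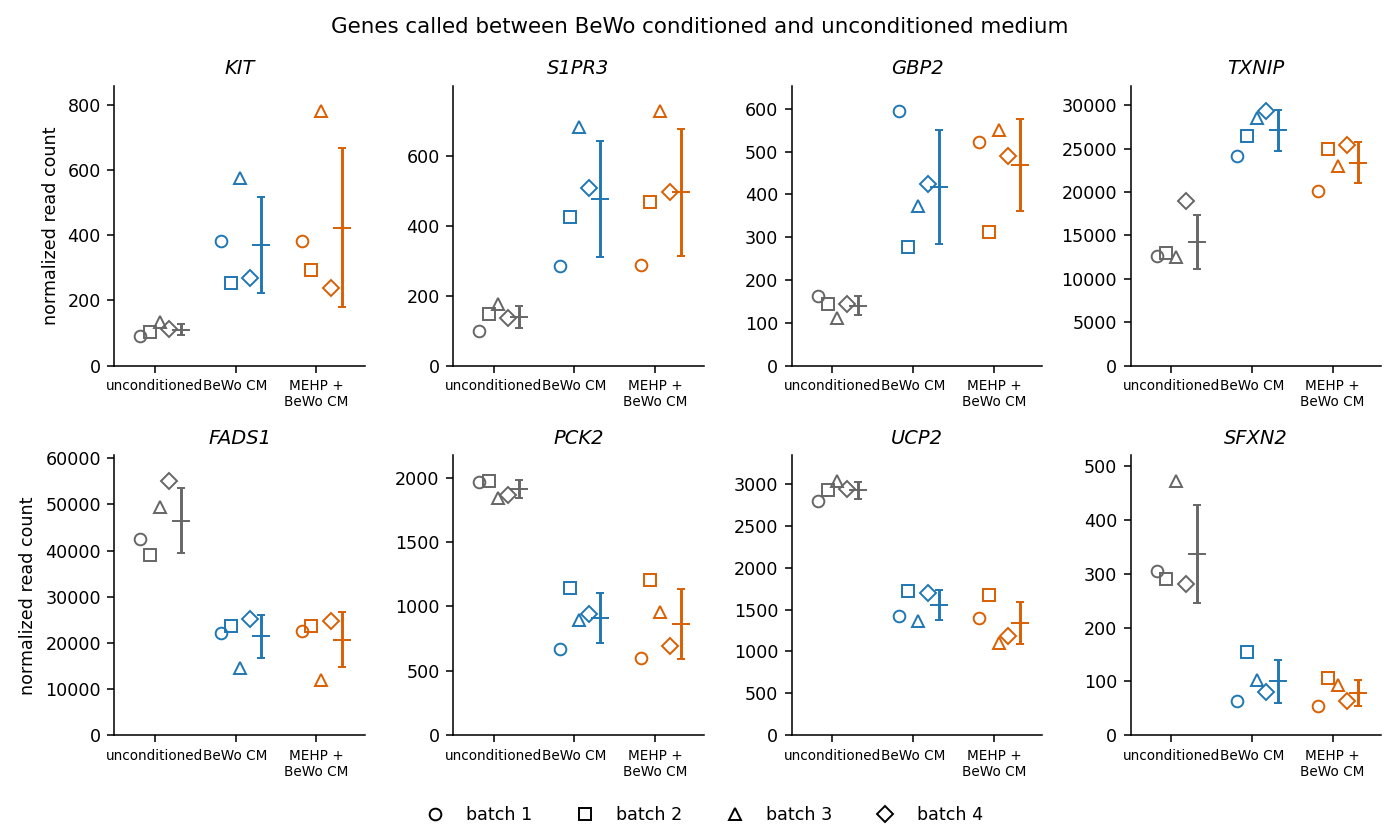
Normalized read counts of KIT, S1PR3, GBP2, TXNIP, FADS1, PCK2, UCP2 and SFXN2 in the 3 media, on linear axes from 0. Points are libraries marked by batch, and bars show the mean ± SD of 4 libraries, with KIT averaging 110.0 in unconditioned, 369.8 in BeWo-conditioned medium and 424 with MEHP.

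In all, 905 of 12811 genes changed between BeWo-conditioned and unconditioned medium, 524 higher and 381 lower (limma, adjusted p under 0.05). Of these, 100 rose and 43 fell beyond 2-fold, and 903 had the same sign in all 4 batches. With the batch as a block the count was 3734 (1932 higher, 1802 lower), and it included all 905. With TMM factors on top of the deposited values the split was 452 higher and 496 lower, and edgeR on the recovered reads gave 441 and 476. The count was 589 without U1, 329 without U3, 297 without U4, 255 without B3 and 496 without B4. Leaving out whole batches without a block gave 966, 535, 72 and 8 genes for batches 1 to 4. With the block kept the counts were 2776, 3265, 2438 and 2249, and they included 900, 904, 893 and 883 of the 905.

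In BeWo-conditioned medium, 4 of 27 G2/M genes rose and 0 fell (7 and 0 adjusted over the list alone, 12 and 2 with the block), among them the mitotic kinase gene PLK1 (0.53 ± 0.10) and the kinesin gene KIF20A (0.71 ± 0.14), and the others were CDC20 (0.64) and NUSAP1 (0.32). The list was shifted upward (camera adjusted p = 0.000922, and adjusted p = 0.487 with an estimated correlation). Of 27 G1/S and DNA replication genes, 0 rose and 2 fell, POLA1 (-0.78 ± 0.19) and DHFR (-0.79 ± 0.22), with 0 and 3 adjusted over the list alone. This list was shifted downward (camera adjusted p = 0.00681, and adjusted p = 0.624 with an estimated correlation), and with the block 3 members rose and 14 fell. Among 18 arrest and apoptosis genes 5 rose and 1 fell (10 and 1 adjusted over the list alone, 11 and 1 with the block). TXNIP, an inhibitor of thioredoxin, rose from 14268 ± 3112 to 27105 ± 2316 (0.94 ± 0.13, limma adjusted p = 0.00259) and its relative ARRDC4 by 0.74 ± 0.14. BTG1 (0.54), BTG2 (1.12) and BAK1 (0.50) rose too, and BAX fell (-0.50). The camera adjusted p of this list was 0.00103 (adjusted p = 0.289 with an estimated correlation). In the same libraries CGA had 1752 reads against 1. NUSAP1 (U3, U4, B1, B2, B3, limma adjusted p 0.0541 to 0.0963) and POLA1 (U3, U4, B3, B4, limma adjusted p 0.0656 to 0.086) lost their calls without 1 library. DHFR (U2, U3, U4, B1, B3, B4, limma adjusted p 0.078 to 0.141) and BTG1 (U3, U4, B3, limma adjusted p 0.0656 to 0.0877) lost their calls without 1 library. BAK1 (U1, U3, B2, B3, B4, limma adjusted p 0.0516 to 0.0999) and BAX (U3, U4, B3, limma adjusted p 0.0514 to 0.0657) lost their calls without 1 library. The G1/S genes (B1, camera adjusted p 0.136) lost the list call without 1 library.

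The fatty acid synthesis list (camera adjusted p = 0.00896, and adjusted p = 0.289 with an estimated correlation) and the cholesterol list (camera adjusted p = 0.00681, and adjusted p = 0.613 with an estimated correlation) were shifted downward in BeWo-conditioned medium. Of 16 fatty acid synthesis genes, 1 rose and 4 fell (1 and 8 adjusted over the list alone, 1 and 8 with the block). The desaturase gene FADS1 went from 46502 ± 7127 to 21444 ± 4685 (-1.13 ± 0.22, limma adjusted p = 0.00959), and the other falls were FASN, fatty acid synthase (-0.64 ± 0.14), SCD (-0.45) and ACACA (-0.34). The member that rose was ME1 (0.35), the malic enzyme that supplies NADPH. Of 26 cholesterol genes 0 rose and 3 fell (0 and 4 adjusted over the list alone, 0 and 11 with the block): HMGCS1 (-0.57 ± 0.13), TM7SF2 (-0.63 ± 0.13) and INSIG1 (-0.80). The low-density lipoprotein receptor gene LDLR was at -0.04 ± 0.10 and did not pass. In the same libraries CGA had 1752 reads against 1. FASN (U3, U4, B3, limma adjusted p 0.0546 to 0.0717) and SCD (U2, U4, B3, limma adjusted p 0.0567 to 0.0974) lost their calls without 1 library. ACACA (U2, U3, U4, B3, B4, limma adjusted p 0.0771 to 0.117) and ME1 (U1, U3, U4, B2, B3, B4, limma adjusted p 0.0511 to 0.0993) lost their calls without 1 library. HMGCS1 (U3, U4, B3, B4, limma adjusted p 0.057 to 0.0777) and TM7SF2 (B3, limma adjusted p 0.052) lost their calls without 1 library. INSIG1 (U3, U4, B3, limma adjusted p 0.0762 to 0.0815) lost its call without 1 library. The cholesterol genes (U2, camera adjusted p 0.129) lost the list call without 1 library.

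The interferon response list (camera adjusted p = 0.00297, and adjusted p = 0.274 with an estimated correlation) and the oxidative stress list (camera adjusted p = 0.00681, and adjusted p = 0.613 with an estimated correlation) were shifted upward in BeWo-conditioned medium. Of 22 interferon response genes 4 rose and 0 fell, with the same numbers adjusted over the list alone (9 and 2 with the block). GBP2, an interferon-induced guanylate-binding protein, rose from 140.2 ± 21.7 to 417 ± 133 (1.53 ± 0.23, limma adjusted p = 0.00326), TAP1, a peptide transporter of antigen presentation, by 0.93 ± 0.15, PSMB9 by 1.33 and IFIT1 by 1.21. Among 20 oxidative stress genes under NRF2, 4 rose and 0 fell (5 and 0 adjusted over the list alone, 11 and 1 with the block): AKR1C3 (1.28 ± 0.27), GSR (0.44 ± 0.09), AKR1C1 (0.76) and ME1 (0.35), where the AKR1C genes are near-identical copies that can share reads. In the same libraries CGA had 1752 reads against 1. IFIT1 (U1, U3, U4, B3, B4, limma adjusted p 0.0569 to 0.0993) and AKR1C3 (U3, B3, limma adjusted p 0.0525 to 0.0553) lost their calls without 1 library. GSR (U4, B3, limma adjusted p 0.0592 to 0.0612) and AKR1C1 (U1, U2, U3, U4, B3, B4, limma adjusted p 0.0581 to 0.128) lost their calls without 1 library. ME1 (U1, U3, U4, B2, B3, B4, limma adjusted p 0.0511 to 0.0993) lost its call without 1 library.

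Of 26 immediate early genes 4 rose and 0 fell in BeWo-conditioned medium, also when adjusted over the list alone (10 and 0 with the block): FOSL2 (0.88 ± 0.17), ETV5 (0.58 ± 0.12), JUN (1.28) and IER5 (0.51). The list was shifted upward (camera adjusted p = 0.00939, and adjusted p = 0.624 with an estimated correlation). Of 19 endoplasmic reticulum chaperone and unfolded protein response genes, HSP90B1 rose (0.61 ± 0.17) and 0 fell (2 and 0 adjusted over the list alone, 10 and 0 with the block). This list was shifted upward too (camera adjusted p = 0.0124, and adjusted p = 0.624 with an estimated correlation). JUN (U1, U2, U4, B1, B3, B4, limma adjusted p 0.0547 to 0.117) and IER5 (U1, U2, U4, B3, B4, limma adjusted p 0.0511 to 0.0929) lost their calls without 1 library. HSP90B1 (U1, U3, U4, B1, B2, B3, B4, limma adjusted p 0.0624 to 0.146) lost its call without 1 library. The immediate early genes (B3, camera adjusted p 0.0809) and the chaperone genes (U3, U4, B2, camera adjusted p 0.0731 to 0.083) lost the list call without 1 library. These 10 lists were the ones past the camera threshold of 27 tested. With the block the myeloid list (0.0185) and the steroid hormone receptor targets (0.0293) also passed upward by the camera adjusted p (adjusted p = 0.358 for both with the block and an estimated correlation). In these libraries, too, CGA had 1752 reads against 1.

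Erythroid genes changed singly in BeWo-conditioned medium, and their list did not pass. Of 29 erythroid genes 5 rose and 0 fell, also adjusted over the list alone, with TMCC2 at 0.81 ± 0.16 and ERMAP at 0.74 ± 0.15, TAL1 at 0.36, GYPE at 0.82 and XPO7 at 0.31 (camera adjusted p = 0.0968 without the block). With the block 11 erythroid genes rose and 4 fell. The erythroid regulators GATA1 (0.15 ± 0.12) and KLF1 (0.05 ± 0.14) and the transferrin receptor gene TFRC (0.00 ± 0.27) did not pass, nor did MYC (-0.03 ± 0.13). Of 7 tested globin genes 0 passed, with a median of -0.50 (camera adjusted p = 0.159), while with the block 1 rose and 4 fell. HBG2 was at -0.50 ± 0.29 (limma adjusted p = 0.308, with the block 0.00252) and HBZ at -0.79 ± 0.59 (0.454, with the block 0.00735), whereas HBG1 was at -0.25 ± 0.22 and passed in neither fit, and HBG1 and HBG2 can share reads. In heme synthesis and iron handling 2 rose and 3 fell of 23 (4 and 3 adjusted over the list alone, 5 and 4 with the block), with ALAD at 0.50 ± 0.13, UROD at -0.56 ± 0.11, UROS at -0.58, STEAP3 at -0.53 and NCOA4 at 0.40. Of 39 amino acid response genes 0 rose and 2 fell (3 and 5 with the block), PCK2 from 1911 ± 68.4 to 911 ± 197 (-1.09 ± 0.19) and CBS (-0.89 ± 0.18), with the same numbers adjusted over the list alone. ASNS, a marker of that response, was at 0.13 ± 0.30 and did not pass. Among 13 PPAR target genes UCP2 fell (-0.92 ± 0.12) and ACOX1 rose (0.50 ± 0.10), also adjusted over the list alone, while PLIN2 (0.15 ± 0.12) and CPT1A (-0.34 ± 0.21) did not pass, CPT1A passing with the block (0.0213, members rising and falling then being 1 and 3). Of 18 replication-dependent histone genes, near-identical copies that can share reads, 0 rose and 2 fell (0 and 4 adjusted over the list alone, 1 and 6 with the block), HIST1H2AI (-0.85 ± 0.16) and HIST1H3H (-0.58 ± 0.12). CGA had 1752 reads against 1 in these libraries. TAL1 (U3, B3, limma adjusted p 0.0591 to 0.0715) and GYPE (U2, U3, U4, B3, B4, limma adjusted p 0.0579 to 0.089) lost their calls without 1 library. XPO7 (U1, U3, U4, B1, B2, B3, B4, limma adjusted p 0.0533 to 0.104) and ALAD (U1, U2, U3, U4, B1, B3, B4, limma adjusted p 0.0599 to 0.0877) lost their calls without 1 library. UROS (U2, U3, U4, B1, B2, B4, limma adjusted p 0.0523 to 0.1) and STEAP3 (U1, U2, U3, U4, B2, B3, B4, limma adjusted p 0.0545 to 0.114) lost their calls without 1 library. NCOA4 (U1, U2, U3, U4, B2, B3, B4, limma adjusted p 0.0585 to 0.129) and CBS (B3, limma adjusted p 0.0507) lost their calls without 1 library. ACOX1 (U4, limma adjusted p 0.0518) lost its call without 1 library.

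In the remaining lists few members passed between BeWo-conditioned and unconditioned medium. Members rising and falling were 1 and 0 of 11 stem and progenitor genes, where KIT was the one that rose, 0 and 1 of 8 megakaryocyte genes, 3 and 1 of 31 glycolysis and hypoxia genes, 1 and 1 of 13 JAK-STAT targets, 1 and 0 of 12 TGF-beta and BMP targets and 1 and 1 of 12 steroid hormone receptor targets. No member passed among 8 myeloid, 5 lymphoid, 18 heat shock, 16 NF-kB and inflammatory and 13 mitochondrially encoded genes, nor among 4 metallothionein and zinc and 3 aryl hydrocarbon receptor genes, which were too few for a list test. Adjusted over the list alone, the numbers were 4 and 1 for glycolysis and hypoxia, 3 and 3 for JAK-STAT, 1 and 1 for TGF-beta and 3 and 1 for steroid targets, and the others gave the same numbers. The genes behind these counts were GP6 (-0.92 ± 0.20), BNIP3L (0.61 ± 0.12), P4HA1 (0.55 ± 0.11), NDRG1 (0.86), PFKL (-0.69), SOCS2 (0.47 ± 0.12), STAT5A (-0.57 ± 0.14), SERPINE1 (1.08 ± 0.25), ERRFI1 (1.01 ± 0.22) and FKBP5 (-0.36 ± 0.10). With the block the members rising and falling were 2 and 0 for stem and progenitor, 1 and 2 for megakaryocyte, 6 and 6 for glycolysis and hypoxia, 4 and 3 for JAK-STAT, 3 and 2 for TGF-beta, 5 and 1 for steroid, 3 and 0 for myeloid, 1 and 1 for lymphoid, 1 and 6 for heat shock, 5 and 1 for NF-kB, 2 and 0 for mitochondrial, 2 and 0 for metallothionein and 1 and 0 for aryl hydrocarbon receptor genes. GP6 (U3, U4, B3, limma adjusted p 0.056 to 0.0608) and NDRG1 (U2, U3, U4, B1, B3, B4, limma adjusted p 0.059 to 0.126) lost their calls without 1 library. PFKL (U3, U4, B3, limma adjusted p 0.0602 to 0.0836) and SOCS2 (U1, U2, U3, U4, B1, B3, limma adjusted p 0.0529 to 0.104) lost their calls without 1 library. STAT5A (U2, U3, U4, B3, limma adjusted p 0.0601 to 0.0929) and SERPINE1 (U1, U3, U4, B3, limma adjusted p 0.0541 to 0.082) lost their calls without 1 library. ERRFI1 (U4, B3, limma adjusted p 0.0628 to 0.0665) and FKBP5 (U1, U2, U3, U4, B1, B3, B4, limma adjusted p 0.0527 to 0.141) lost their calls without 1 library. The camera adjusted p of these lists lay between 0.082 and 0.945, and the remaining camera adjusted p values were 0.89 for heme, 0.326 for amino acid response, 0.678 for PPAR targets and 0.0968 for histones. The median and mean of the list had opposite signs in the megakaryocyte (0.08 and -0.03, tested downward) and lymphoid lists (0.12 and -0.02, tested upward).

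**Figure D3:**
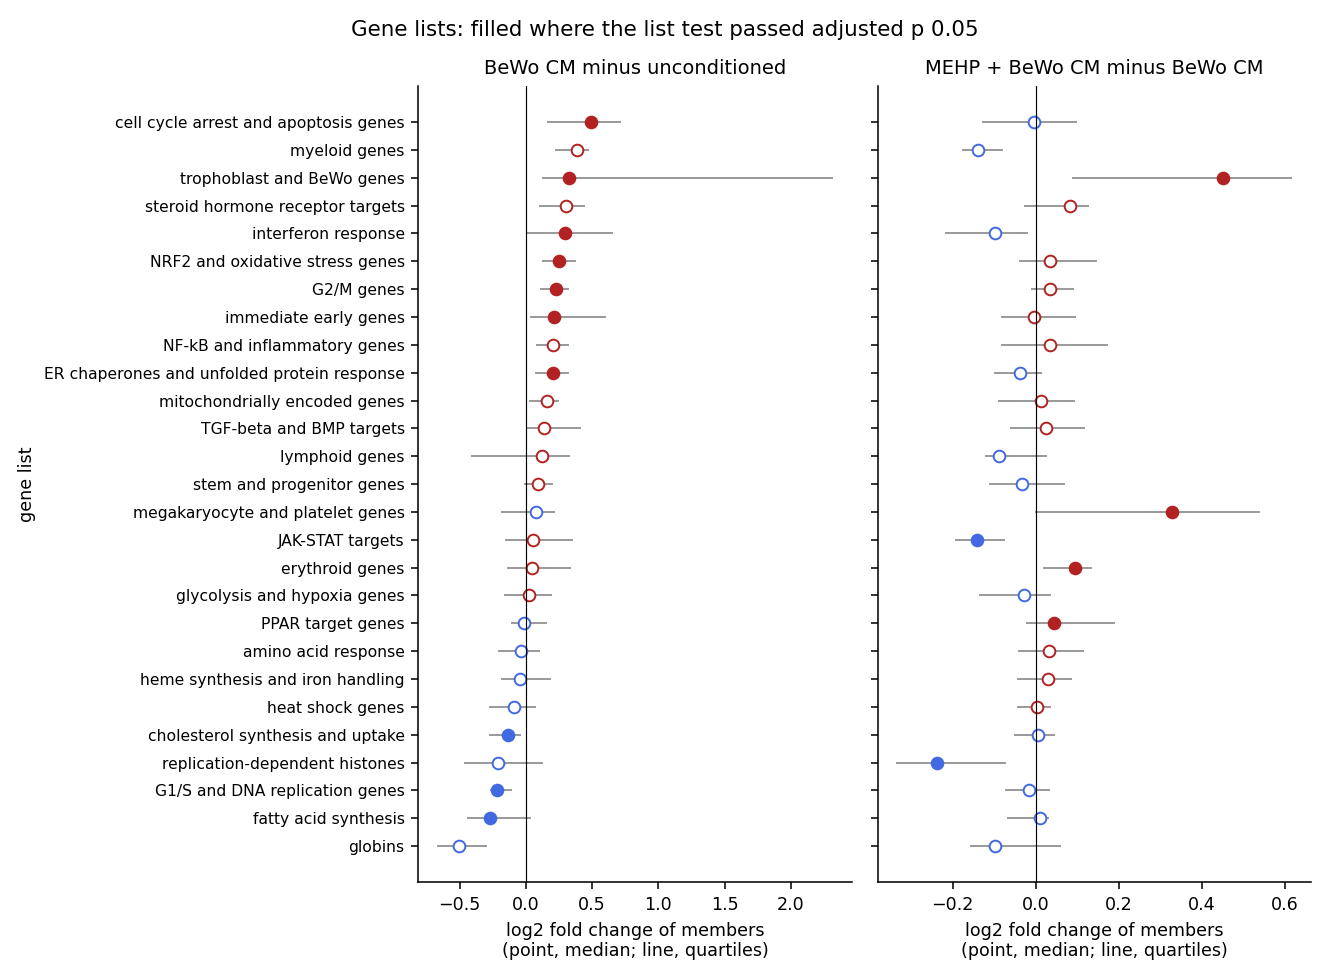
Median log2 fold change of the tested members of each gene list (points) with quartiles (lines), for BeWo-conditioned minus unconditioned medium and for MEHP with BeWo-conditioned minus BeWo-conditioned medium. Red marks lists tested upward and blue lists tested downward, and filled points have a camera adjusted p under 0.05, as 10 and 6 of the 27 tested lists had.

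MEHP within conditioned medium was compared next, and no gene passed. The smallest p values belonged to PLIN2, the lipid droplet coat protein (chromosome 9, 19108375 to 19149290, minus strand), COL4A1, CLDN4, a claudin, PDK4, a pyruvate dehydrogenase kinase (chromosome 7, 95583499 to 95596491, minus strand), and GATA3. Each was higher with MEHP in 4 of 4 batches by normalized count, in genes picked for their small p values. Some of these signs rest on few reads: GATA3 in batch 4 had 8 reads without and 7 with MEHP (8.61 and 9.2 normalized), and PDK4 in batch 1 had 5 and 7 reads. PLIN2 was at 1664 ± 141 in BeWo-conditioned medium and 2354 ± 404 with MEHP (0.49 ± 0.12), and at 1498 ± 106 in unconditioned medium. PDK4 was at 7.25 ± 2.88 and 38.7 ± 30.0 (1.92 ± 0.56, and 2.56 without M1), CLDN4 at 14.9 ± 5.62 and 33.1 ± 5.25 (1.17 ± 0.33), COL4A1 at 10.4 ± 6.69 and 45.1 ± 27.9 (1.93 ± 0.50) and GATA3 at 7.66 ± 0.711 and 24.6 ± 11.3 (1.42 ± 0.44). CPT1A, the carnitine palmitoyltransferase of fatty acid oxidation, was at 1258 ± 449.9 and 1741 ± 388 (0.50 ± 0.21, 4 of 4 batches). CLDN4 with MEHP (27.55 to 39.35) was near its unconditioned level (30.89 to 66.53), and it was lower in BeWo-conditioned medium (6.9 to 19.36). CPT1A with MEHP (1353 to 2225) overlapped its unconditioned range (1337 to 1894). At adjusted p under 0.05 limma called 0 of 12811 genes, and 123 had an unadjusted p under 0.05.

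The other tools called 0 genes with MEHP without a block, at 129 unadjusted for edgeR and 127 for DESeq2. With the batch as a block limma and edgeR still called 0, at 784 and 746 unadjusted, and the smallest adjusted p was 0.0707 in limma and 0.0654 in edgeR, both for PLIN2. DESeq2 with the block called 6: PLIN2 (0.49 ± 0.08, adjusted p = 1.2e-05), TFRC (0.40 ± 0.08), CPT1A (0.50 ± 0.11), COL4A1 (2.08 ± 0.48) and PDK4 (2.22 ± 0.52) higher, and DHRS2, named after its value was seen, lower (-0.41 ± 0.09), the highest adjusted p among them being 0.0382. In simulated counts of the comparison of BeWo-conditioned with unconditioned medium, DESeq2 with the block made 23 false calls. There 50 genes were changed at each fold, and 100% of those changed 2-fold were recovered, so true calls stood beside the false ones. The comparison with MEHP was not simulated, so the 23 cannot be set against its 6 calls, and how many of these are false is not known. Over the alternatives run, the adjusted p of PLIN2 went from 1.2e-05 to 1. Trophoblast reads also differed between these media: CGA had 3652 reads with MEHP and 1752 without, a ratio of 2.03 (95% interval 1.92 to 2.15), and PDK4 had 150 and 28, a ratio of 5.22 (95% interval 3.47 to 8.12). CGA was higher with MEHP in batches 1 to 3 and lower in batch 4, where its normalized count was 97.2 with MEHP and 139.8 without.

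**Figure D4:**
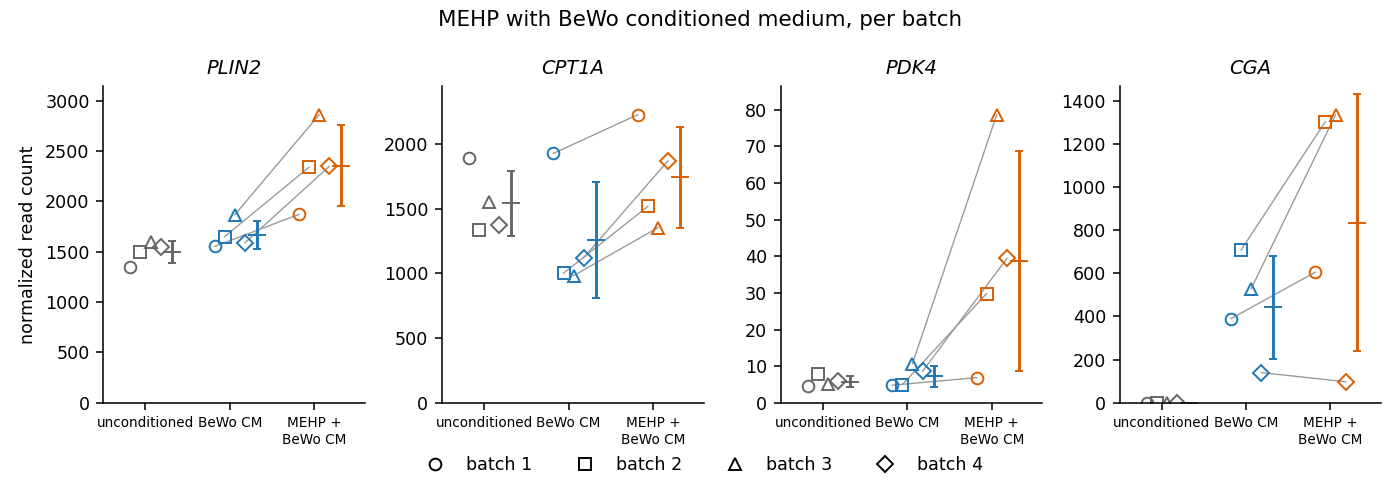
Normalized read counts of PLIN2, CPT1A, PDK4 and CGA in the 3 media. Points are libraries, lines join the BeWo-conditioned libraries without and with MEHP of a batch, and bars show the mean ± SD of 4 libraries, with PLIN2, CPT1A and PDK4 higher with MEHP in each batch and CGA in batches 1 to 3.

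With MEHP 6 of 27 lists were past the camera threshold, in libraries with 3652 CGA reads against 1752, and 0 members passed over all genes (limma). The histone genes, near-identical copies that can share reads, were shifted downward (median -0.24, camera adjusted p = 1.92e-05, and adjusted p = 0.224 with an estimated correlation) and the trophoblast and BeWo genes upward (median 0.45, camera adjusted p = 0.000224, and adjusted p = 0.111 with an estimated correlation). PPAR target genes were shifted upward with a median of 0.04 and a mean of 0.25 (camera adjusted p = 0.0054, and adjusted p = 0.356 with an estimated correlation), and 2 members, PLIN2 and PDK4, passed adjusted over the list alone. Members of this list did not all move alike. UCP2 was lower with MEHP in each batch (1395 against 1428 in batch 1, 1184 against 1695 in batch 4), and ACOX1 had no common direction. Megakaryocyte genes (median 0.33, camera adjusted p = 0.0054) and erythroid genes (median 0.09, 0.0418) were shifted upward and JAK-STAT targets (median -0.14, 0.0138) downward (adjusted p = 0.111, 0.904 and 0.329 with an estimated correlation). The erythroid call ended with TMM factors (camera adjusted p = 0.0501), and with the block the myeloid list was shifted downward (0.0145, and adjusted p = 0.333 with the block and an estimated correlation). Histones (B1, camera adjusted p 0.112) and PPAR targets (B1, M2, camera adjusted p 0.0858 to 0.193) lost the list call without 1 library. Megakaryocyte genes (B1, camera adjusted p 0.0871) and erythroid genes (B1, B2, M1, M3, M4, camera adjusted p 0.0592 to 0.538) lost the list call without 1 library. JAK-STAT targets (B1, M2, M3, M4, camera adjusted p 0.0581 to 0.147) lost the list call without 1 library. Without B1 the number of lists was 1, the trophoblast list, and that call ended without batch 1 (camera adjusted p = 0.0773). The other 21 tested lists had camera adjusted p values from 0.0778 to 0.966, with 0 members passing over all genes or adjusted over the list alone. Among them the median and mean had opposite signs for cholesterol (0.01 and -0.01) and fatty acid synthesis (0.01 and -0.03), both tested downward, and for immediate early genes (-0.00434 and 0.013, tested upward).

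BeWo-conditioned medium with MEHP was also set against unconditioned medium. CGA rose by 8.92 ± 0.69 and MMP2 by 6.31 ± 0.63 (limma adjusted p = 3.03e-05 and 0.000265), with 3652 and 771 reads against 1 and 4. Without M4, where CGA and MMP2 were at 97.2 and 28.9 normalized counts, the rises were 9.76 and 7.01. The depth-corrected ratios were 3832 (95% interval 687 to 151379) and 202 (95% interval 78.7 to 744). KIT reached 424 ± 245 (1.79 ± 0.32), and the lipase gene LIPH rose from 156 ± 37.3 to 709 ± 456 (2.00 ± 0.40). The other largest rises were HID1 (2.26 ± 0.44), HMCN1 (2.06 ± 0.46), EMILIN2 (2.05 ± 0.46), YPEL4 (2.04 ± 0.40) and CRYBG1 (1.98 ± 0.31). SFXN2 went to 79.2 ± 24.3 (-2.09 ± 0.28) and PYCR3 to 151 ± 32.7 (-1.88 ± 0.21, limma adjusted p = 0.000338). The other largest falls were VPS9D1-AS1 (-1.91 ± 0.30), ACE (-1.77 ± 0.36), PTPRVP (-1.72 ± 0.48), CARD9 (-1.65 ± 0.41), EEF2KMT (-1.46 ± 0.22) and ELFN1-AS1 (-1.44 ± 0.36). ELFN1-AS1, annotated as a lincRNA, lies within ELFN1 on the opposite strand, so the limit on strand applies to it. It can also apply to EEF2KMT, which overlaps ALG1 on the opposite strand. PLIN2 rose by 0.64 ± 0.12 (limma adjusted p = 0.00413), and TFRC (0.40 ± 0.27) passed with the block alone (0.000401), as did HBG1 (-0.36 ± 0.22, 0.0214), HBG2 (-0.40 ± 0.29, 0.00677), HBZ (-0.78 ± 0.59, 0.00604) and MYC (-0.20 ± 0.13, 0.0352). PTPRVP (U1, U3, M2, M3, M4, limma adjusted p 0.0571 to 0.083) and CARD9 (M3, limma adjusted p 0.0606) lost their calls without 1 library. ELFN1-AS1 (U3, limma adjusted p 0.0518) lost its call without 1 library.

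Here 1894 genes changed, 996 higher and 898 lower (limma, adjusted p under 0.05), 170 rising and 106 falling beyond 2-fold. With the block 4897 changed (2512 higher, 2385 lower), including all 1894. The count was 983 without U3, 1047 without U4, 940 without M3 and 1202 without M4. Without batches 1 to 4 it was 2446, 1249, 371 and 167 with no block, and 4349, 4249, 3286 and 3352 with the block kept.

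Against unconditioned medium 11 lists passed the camera test with MEHP, 7 of them upward, in libraries where CGA had 3652 reads against 1. Trophoblast and BeWo genes (6 rose and 0 fell, with the block 8 and 0, camera adjusted p = 0.000205, and adjusted p = 0.195 with an estimated correlation) included CGA (8.92), GATA3 (3.81) and CDH1 (1.98). G2/M genes (6 rose and 0 fell, with the block 17 and 0, camera adjusted p = 0.000205, and adjusted p = 0.455 with an estimated correlation) included PLK1 (0.47), AURKA (0.63) and KIF20A (0.72). Of the arrest and apoptosis genes (5 rose and 1 fell, with the block 10 and 1, camera adjusted p = 0.00337, and adjusted p = 0.421 with an estimated correlation) the rises were TXNIP (0.73), ARRDC4 (0.75), BTG1 (0.61), BTG2 (1.26) and KLF6 (0.59) and the fall BAX (-0.52). NRF2 genes (6 rose and 0 fell, with the block 12 and 1, camera adjusted p = 0.00646, and adjusted p = 0.636 with an estimated correlation) included AKR1C3 (1.70), GSR (0.46) and ME1 (0.45). Erythroid genes (7 rose and 0 fell, with the block 12 and 3, camera adjusted p = 0.0235, and adjusted p = 0.636 with an estimated correlation) included TAL1 (0.44), TMCC2 (0.93) and ERMAP (0.84). Immediate early genes (5 rose and 0 fell, with the block 10 and 2, camera adjusted p = 0.0303, and adjusted p = 0.67 with an estimated correlation) rose in FOSL2 (1.14), JUN (1.35), IER5 (0.53), ETV5 (0.52) and PHLDA1 (1.10). Of the interferon response genes (4 rose and 2 fell, with the block 7 and 3, camera adjusted p = 0.0476, and adjusted p = 0.421 with an estimated correlation) the rises were IFIT1 (1.70), GBP2 (1.72), PSMB9 (1.07) and TAP1 (0.87) and the falls IFI35 (-0.73) and IFITM1 (-0.36), and the list call ended with the block (0.0644). KLF6 (M3, limma adjusted p 0.0533) and JUN (U4, M3, limma adjusted p 0.0564 to 0.0631) lost their calls without 1 library. PHLDA1 (U2, M3, M4, limma adjusted p 0.0619 to 0.0643) and IFI35 (U3, M3, limma adjusted p 0.0529 to 0.0597) lost their calls without 1 library. IFITM1 (U2, U3, U4, M3, M4, limma adjusted p 0.0648 to 0.131) lost its call without 1 library. Erythroid genes (U2, M4, camera adjusted p 0.0681 to 0.153) and immediate early genes (U1, U2, U4, M1, M3, camera adjusted p 0.0673 to 0.129) lost the list call without 1 library. Interferon response genes (U2, U4, M1, M4, camera adjusted p 0.0611 to 0.116) lost the list call without 1 library.

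The other 4 lists were shifted downward with MEHP against unconditioned medium, again with 3652 CGA reads against 1. Histone genes (0 rose and 6 fell, with the block 1 and 7, camera adjusted p = 0.00366, and adjusted p = 0.421 with an estimated correlation) included HIST1H3H (-0.85 ± 0.12). Of the G1/S genes (1 rose and 3 fell, with the block 1 and 16, camera adjusted p = 0.0131, and adjusted p = 0.67 with an estimated correlation) the rise was E2F1 (0.38) and the falls CDC45 (-0.43), DHFR (-0.94) and POLA1 (-0.84). Cholesterol genes (0 rose and 4 fell, with the block 1 and 12, camera adjusted p = 0.0131, and adjusted p = 0.636 with an estimated correlation) fell in HMGCS1 (-0.52), FDPS (-0.40), INSIG1 (-0.80) and TM7SF2 (-0.86). Among fatty acid synthesis genes (1 rose and 6 fell, with the block 1 and 8, camera adjusted p = 0.0183, and adjusted p = 0.421 with an estimated correlation) the rise was ME1 (0.45), and FADS1 (-1.21 ± 0.22) was among the falls. E2F1 (U1, U2, U3, U4, M3, M4, limma adjusted p 0.0635 to 0.12) and CDC45 (U3, M3, limma adjusted p 0.0597 to 0.0631) lost their calls without 1 library. DHFR (U3, limma adjusted p 0.0523) and HMGCS1 (U3, M3, limma adjusted p 0.05 to 0.0685) lost their calls without 1 library. FDPS (U2, U3, U4, M1, M3, limma adjusted p 0.0698 to 0.0956) lost its call without 1 library. G1/S genes (M1, camera adjusted p 0.101) and cholesterol genes (U2, camera adjusted p 0.123) lost the list call without 1 library. Adjusted over the list alone the members rising and falling were 7 and 0 for trophoblast, 7 and 0 for G2/M, 6 and 1 for arrest, 8 and 1 for NRF2, 10 and 0 for erythroid, 5 and 0 for immediate early, 4 and 2 for interferon, 1 and 6 for histone, 1 and 3 for G1/S, 0 and 4 for cholesterol and 1 and 7 for fatty acid genes. With the block the chaperone list (0.0225) and steroid targets (0.0236) were shifted upward and globins (0.0407) downward (adjusted p = 0.482, 0.416 and 0.424 with the block and an estimated correlation). The other 16 tested lists had camera adjusted p values from 0.056 to 0.963. Median and mean had opposite signs for amino acid response (0.01 and -0.03, tested downward), heme (0.05 and -0.00457, tested upward) and glycolysis genes (-0.03 and 0.01, tested upward).

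The comparisons with unconditioned medium share their 4 control libraries. They had 836 called genes in common, 490 higher and 346 lower in both, and 0 in opposite directions, which is 92.4% of the genes called without MEHP (3269 with the block). Independent lists of these sizes would share 40.7 higher and 26.7 lower genes. In 100 simulations of unchanged groups against shared controls the mean overlap was 3.3 higher and 2.27 lower genes, and the highest was 330 and 227. With the controls split 2 and 2 between the comparisons, the mean over 6 splits was 62.2 higher and 30.7 lower shared genes. The lists were smaller there too, with means of 122 higher and 61.7 lower genes called without MEHP and 373.5 and 282 with it. Across genes, which are not independent replicates, the fold changes correlated with r = 0.918 against a mean of 0.48 in the simulations (highest 0.919) and 0.699 with split controls, and their covariance was 0.156 against a simulated mean of 0.0278 (highest 0.114), a difference of 0.129. With split controls the covariance was 0.134 on average (0.126 to 0.138). The simulated value leaves out real effects and the independent lists leave out the shared controls, so neither excess measures a shared effect. The overlap was 313 without U3, 289 without U4, 250 without B3 and 482 without B4, and 866, 500, 70 and 8 without batches 1 to 4.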

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

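The counts of appearing genes and of other splits of the libraries were planned, and the other tests in this part (CGA on the wrong side, K-562 cells switching genes on, falls, rises, rises by library, GC content, batch 4) were chosen after the results were seen.

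Trophoblast transcripts appeared in the conditioned libraries, such as the list members CGA with 1752 reads, CGB8 with 47 and GATA3 with 30, against 1, 0 and 3 in unconditioned medium. No library had CGA on the wrong side (0 libraries with over 3 reads in unconditioned or 3 or fewer in conditioned medium), which argues against a library mislabelled between unconditioned and conditioned medium. An exchange between the conditioned media would not show in this count. BeWo RNA or cells carried over with the medium, which the PBS wash would have to leave behind, and K-562 cells switching the genes on both stay open. Genes appearing in BeWo-conditioned medium outnumbered those disappearing by 1.86 (136 against 73; 2.52 with MEHP, 189 against 75), which lies between the bounds set beforehand of 3 for carry-over and 1.5 against it. All 8 conditioned libraries had over 3 CGA reads, as either explanation would have it, so the sources cannot be told apart here.

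The second pattern is the change of genes that K-562 cells express: carried-over RNA adds reads, yet 26 genes with an unconditioned mean of at least 50 fell beyond 2-fold, so it cannot account for the falls, and 797 of the 905 calls stayed after a correction for GC content and length. For the rises it stays open: with carry-over, the rise with MEHP divided by the rise without should be near that of genes silent in unconditioned medium, and its median was 1.22 (quartiles 1.06 to 1.42) over 860 genes called higher with MEHP against unconditioned medium and 1.09 (quartiles 0.934 to 1.23) over 451 called higher in BeWo-conditioned medium. Silent genes chosen by their BeWo-conditioned reads, the set tried first, had a median of 1.09 (quartiles 0.544 to 1.90) and would go with carry-over, while a set chosen on both conditioned media together, added after that outcome because the first choice favours low ratios, had 1.75 (quartiles 1.09 to 2.77), above both medians. By library, CGA, MMP2 and the summed silent genes, as shares of their medium's mean, all lay outside the quartiles of the rises in 2 of 8 libraries: M4 (0.116, 0.164 and 0.38 against a median rise of 0.955) and M2 (1.56, 1.59 and 1.14 against 0.719), which goes against carry-over as the whole cause with MEHP. In BeWo-conditioned medium 0 libraries did so, and in B4 CGA (0.317) and the silent genes (0.865) parted around the lower quartile of the rises (0.797). These tests therefore cannot tell carry-over and a response of the K-562 cells apart for the rises in that medium. For TXNIP the scale can be compared too. It was at 18924 in U4 and 29311 in B4, where CGA was at 140. In batch 2 it was at 13016 in U2 and 26445 in B2, where CGA was at 708. Carry-over of this rise would need far more TXNIP than CGA in BeWo RNA, which was not measured. With MEHP a part from carry-over stays open.

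The third pattern is PLIN2, CPT1A and PDK4 being higher with MEHP, which a response of the K-562 cells may explain but which was not called without a block. No medium held MEHP without BeWo conditioning. A response to MEHP itself therefore cannot be told apart from a response to BeWo cells exposed to it. Of other genes, the PPAR target UCP2 was lower with MEHP in each batch, and TFRC, outside that list, was higher in each. A trend on GC content and length is argued against, since PLIN2 stayed at a log2 difference of 0.51 after that correction with the block. In batch 4, where the log2 difference of CGA was -0.52, the smallest difference of PLIN2, CPT1A and PDK4 was 0.56. PLIN2 went there from 1588 to 2347 normalized counts, while CGA was at 97.25 with MEHP. Other genes near 0 in unconditioned medium disagreed in that batch. With MEHP, MMP2 was lower (28.9 against 51.6 normalized counts), and COL4A1 (15.8 against 8.61) and DSP (13.1 against 7.53) were higher. COL4A1 and DSP rest on few reads there, 12 against 8 and 10 against 7. The batch therefore goes against carry-over as CGA and MMP2 trace it, while COL4A1 and DSP had too few reads to tell. It rests on a single pair of libraries, so carry-over stays open. In DESeq2 with the block 2 of 8 splits that part all pairs gave as many genes (6 in the real split, highest other 8), and 8 splits are too few for a share under 0.05.

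Against unconditioned medium 1 of 35 splits of the libraries gave as many genes as BeWo-conditioned medium (905, highest other 0). For MEHP it was also 1 of 35 (1894, highest other 0). These 35 splits ignore the pairs, so they do not exclude chance. Libraries of a batch are paired, and the 8 splits that part all pairs are too few for a share under 0.05. Among those 8 the real split gave 905 and 1894 (3734 and 4897 with the block) and the others 0 in either fit. Between the conditioned media limma called 0 genes (123 unadjusted, 0 in edgeR and DESeq2 without a block), so all 35 of 35 splits gave as many by construction and say nothing of chance. One of them gave 2182 and parted batches 1 and 4 from 2 and 3, a structure of the samples by batch. That split cannot be fitted with the block, under which the real split gave 0.

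A library stood apart from the other 3 of its medium by its gap ratio in 26 of 270 sets of values tested, where the ratio passed Dixon's 95% critical value for 4 samples, and chance gives about 1 in 20, or 13.5. Gap ratio and library are given for each. In unconditioned medium these were CGA (1, library 1 highest), SFXN2 (0.876, library 3 highest), DBNL (0.893, library 3 highest), GP6 (0.903, library 2 lowest), ACOX1 (0.877, library 2 highest), TXNIP (0.917, library 4 highest), CLDN4 (0.917, library 4 highest), TNFAIP2 (0.987, library 4 lowest) and ID1 (0.891, library 3 highest). In BeWo-conditioned medium these were MMP2 (0.937, library 3 highest), CARD9 (0.871, library 1 highest), FOSL2 (0.83, library 3 highest), CPT1A (0.853, library 1 highest), EMILIN2 (0.82903, library 3 highest), PTPRVP (0.888, library 1 highest), HBQ1 (0.988, library 4 highest) and PFKL (0.833, library 3 lowest). In BeWo-conditioned medium with MEHP these were CRYBG1 (0.895, library 3 highest), CARD9 (0.85, library 1 highest), FADS1 (0.833, library 3 lowest), FOSL2 (0.842, library 3 highest), HIST1H2AI (0.85, library 3 lowest), KLF1 (0.841, library 4 highest), HID1 (0.915, library 3 highest), PTPRVP (0.961, library 1 highest) and ID1 (0.88, library 1 highest). Batch 3 held 12 of the 26. Of the normalized counts behind them, HID1 in library 3 with MEHP was 285 against 77.5 for the next, and CPT1A in BeWo-conditioned library 1 was 1926 against 1121. The ratio is relative to the range of the 4 libraries and is no measure of size: CGA in unconditioned library 1 was 1 read against 0 in the others, and TNFAIP2 in unconditioned library 4 was 1476 against 1558 for the next.

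Entries without a gene name, which no comparison used, were tested in the same way where their mean was at least 10 (1083 entries). In BeWo-conditioned medium 1 was higher and 0 lower (114 changed with the block), with MEHP against unconditioned medium 10 were higher and 28 lower (192 with the block), and between the conditioned media limma called 0 (19 unadjusted, and 0 with the block).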

How the results depend on the processing

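The omission of genes near zero, the GC and length correction, the estimated correlation with the block, batch omission with the block, and library and batch omission for the lists and the overlap were chosen after the data were seen. For BeWo-conditioned against unconditioned medium (905 genes) the count was 3734 with the block, 598 with no filter on low values (557 shared with the 905), 1507 in DESeq2, 3823 in edgeR and 3775 in DESeq2 with the block, 4517 with the GC correction and block, and 3726 without genes near zero and with the block. Leaving out single libraries or batches gave 8 to 966 genes, and with the block kept 2249 to 3265 (2776 and 2438 for the other batches). For MEHP against unconditioned medium (1894 genes) the block gave 4897, edgeR and DESeq2 with the block 4894 and 4789, the GC correction with the block 5470, and the omission of genes near zero with the block 4889. Leaving out libraries or batches gave 167 to 2446, and with the block kept 4349, 4249, 3286 and 3352. For MEHP within conditioned medium the count was 0 in limma, and left 0 in every omission, while DESeq2 with the block gave 6 and the GC correction with the block 1 (PLIN2). The cause of these moves was not tested, apart from fewer libraries or more genes in the test where a setting says so.

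The gene lists past the threshold (10, 6 and 11) came to 0, 0 and 0 with an estimated correlation, and to 0, 0 and 0 with it and the block. Leaving out libraries or batches gave 9 to 13, 1 to 9 and 8 to 14 lists. The overlap of the comparisons (836) was 3269 with the block, 93 with split controls and 8 to 866 with libraries or batches left out. No named gene changed direction where it was called, while some that did not pass changed sign, such as ASNS (-0.12 to 0.33 in BeWo-conditioned medium). Over 30 to 33 alternatives per named gene and comparison, the side of the threshold stayed the same 1833 times and a call was lost 213 times and gained 26 times for BeWo-conditioned medium. The same counts were 2076, 120 and 40 for MEHP against unconditioned medium and 580, 0 and 6 for MEHP within conditioned medium. In the fit without the block, of 52 named and called genes 30 kept their call without any single library and 3 (CGA, MMP2, PYCR3) also without any batch, and of 58 with MEHP 46 and 21 did. Among named genes and lists the block changed no other call than those given with the results. Genes with few reads, such as COL4A1 and GATA3, are limited by depth.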

Other observations

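Other genes nearly silent in unconditioned medium also had reads in conditioned medium, chosen after their values were seen. In unconditioned, BeWo-conditioned and MEHP-containing medium, the summed reads were 0, 31 and 111 for FBLN1, an extracellular matrix gene, 0, 34 and 76 for the imprinted gene PEG3, 1, 21 and 61 for EGFR, the epidermal growth factor receptor gene, and 0, 21 and 48 for the trophoblast transcription factor gene TFAP2C. The chorionic gonadotropin beta genes CGB3, CGB5 and CGB8, which are near-identical and can share reads, had 0 reads in unconditioned medium, 24, 23 and 47 in BeWo-conditioned medium, and 47, 62 and 91 with MEHP. The placental lactogen genes CSH1 and CSH2 and PSG1 had at most 2 reads over any medium. HMOX1, the heme oxygenase gene, had 1, 26 and 89 reads. For these 8 genes with higher sums with MEHP, each of batches 1 to 3 had more reads with MEHP than without, while batch 4 had few reads of either and no common direction. There, without and with MEHP, the reads were 8 and 3 for FBLN1, 2 and 2 for PEG3, 3 and 1 for EGFR, 0 and 1 for TFAP2C, 2 and 0 for CGB3, 3 and 0 for CGB5, 0 and 1 for CGB8, and 2 and 5 for HMOX1.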
